A study of Ambystoma mexicanum with 7 samples.

How the data were processed

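ATAC-seq libraries were made from 7 samples of axolotl limb tissue, 3 of intact limb, 2 of systemically activated limb and 2 of blastema with wound epidermis. Per the labels' protocols, tissue was dissociated enzymatically, live cells with a 4C DNA content were sorted, and sorted cells were transposed with Tn5. Samples were grouped by their labels. Nothing in the labels says whether samples of a group came from separate animals. Replicate numbers in the titles have gaps and some recur between groups, and the labels do not say what either means.

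Reads were aligned with Bowtie2 2.3.2 and peaks were called with MACS2, per the submitters' processing notes. The version of MACS2, the genome build, the handling of duplicates, any shift of reads for the Tn5 cut, the effective genome size and the use of a control are not given in the sources used here. The authors' lists are 1 per group and 1 for all samples, as the labels assign them, so the samples of a group went into 1 list, and how they were combined is not stated. Samples therefore have no values of their own, and depth could be judged per list but not per sample.

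Each peak has a start, an end and a summit offset in bases, and 4 values that the authors deposited. Per peak, the authors deposited a score, which is 10 times the −log10 q without its decimals and was not used further. The fold that the authors deposited is the ratio of the pileup at the summit to the background of the same list. The other values are the −log10 p and the −log10 q at the summit, deposited by the authors as MACS2 writes them, where the q-value is adjusted within 1 list. All are the authors' own values per peak and served only to describe, rank or filter peaks within a list. They move with depth, so a fold or q of 1 list was not set against that of another as a change.

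Positions are printed 1-based on the sequences that the files name. These are 28 chromosome arms, of which 21 are cut into segments, giving 66 segments numbered from 0, and unplaced sequences. For 38 of the 38 segments that have a next segment, the last peak of any list ended before the start written in the name of the next one. Positions are counted within a segment, and the segment number is left out for arms with 1 segment. No genome or annotation known to be of the files' build was used here, and the gene table at hand could not be taken to be of that build. The genes near a peak, its place in exons, introns or promoters, and sequence motifs were therefore not analysed here. That removed 3 planned results: promoter peaks of 15 gene lists, peaks by annotated feature, and 24 motifs at summits.

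A peak counted as shared when an interval of the other list overlapped it by at least 1 base. Shares have exact (Clopper-Pearson) 95% intervals. The chance overlap of a pair of lists came from 1000 random draws of all-sample peaks matched on 10 strata of the all-sample −log10 q. The all-sample list includes the reads of the groups, most of them from blastema by the backgrounds below, so this matching holds constant part of what it compares. Peaks held by 1 limb list were compared for blastema overlap with Fisher's exact test, two-sided, and with Mantel-Haenszel odds ratios within 10 strata. With 1 list per group there was no test between conditions and no replicate could be left out.

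Depth was read from the summit values. The fold and −log10 p of each peak were solved for a whole-number pileup and a background with the MACS2 formulas (fold is pileup plus 1 over background plus 1, and p is a Poisson tail), within a tolerance of 0.001. A single whole pileup was found for 99.9% of intact, 99.8% of systemically activated and 100% of blastema and all-sample peaks. The lowest background of a list was taken as its genome-wide background, at which 181 systemically activated, 1053 intact, 14722 blastema and 87492 all-sample peaks stood. The other backgrounds were multiples of 0.02 in 100% of cases. To ask what a shallower blastema list would hold, the blastema pileups were scaled to the background of each limb list and the expected number of calls past that list's lowest −log10 p was summed. This assumes an equal share of reads in peaks in both groups and starts from summits selected for height, which biases it upward. Windows of 20 Mb and chromosome arms with at least 20 peaks in both lists together had their share of the first list's peaks compared with the genome-wide share by an exact binomial test, two-sided, with Benjamini-Hochberg adjustment within each of 10 sets of tests (5 comparisons at 2 levels).

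The overlap rules, the alternatives in overlap, threshold, list length, merging and sequences, and the rule for named peaks were set before the data were examined. That rule took, in each pairwise comparison and direction, the 5 peaks with the highest fold among those on named arms without an overlap in the other list, and the 5 blastema peaks with the highest fold that both limb lists overlap, which gave 35 entries. The limb lists at equal length with the whole blastema list (dropping the weakest intact peaks, or 100 random draws), the draws matched on 100 strata, the stratified odds ratios, the scaling of pileups with either background, the random draws of blastema peaks over windows, the regional tests and the comparison of all-sample with summed backgrounds were added after seeing the data.

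Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and the overlap and merge routines were checked against bedtools 2.31.1 on simulated intervals. The solving step was tested on pileups simulated for each list and recovered 99.2% of 2954 systemically activated, 99.6% of 2954 intact, 100% of 2999 blastema and 100% of 3000 all-sample pileups.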

Results

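Chromatin accessibility was profiled by ATAC-seq in sorted limb cells of the axolotl, Ambystoma mexicanum, a salamander that regrows its limbs. ATAC-seq uses the Tn5 transposase to tag DNA where it is open, so a peak marks a stretch of accessible chromatin. Cells with a DNA content of 4C, the content of cells that have copied their genome, were isolated by fluorescence-activated cell sorting. DNA content alone does not show that a cell was dividing. The 7 samples fell into 3 groups. The intact group held 3 samples of homeostatic limb, the systemically activated group 2 samples, and the blastema group 2 samples of blastema with wound epidermis. Systemic activation is the return of cells to the cell cycle in limbs that were not themselves injured after an amputation elsewhere in the body. The blastema is the mass of progenitor cells that forms at the stump. The series design gives 14 days after amputation for homeostatic and systemically activated limbs, and the day of the blastema samples is not stated in the sources used here.

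The data were 4 lists of peaks, 1 for each group and 1 for all samples together, so no sample had values of its own. No list had a replicate, and no difference below could be set against a spread between replicates. Intervals are exact binomial 95% intervals over peaks, and they cover counting error only. Every test compares lists of peaks and not conditions.

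As deposited, the blastema list was by far the longest of the group lists. It held 168368 peaks covering 73.0 Mb, against 25843 peaks covering 10.6 Mb in intact limb and 17326 peaks covering 6.48 Mb in systemically activated limb. The blastema list was thus 9.72 times as long as the systemically activated list, and the intact list 1.49 times as long. At a fold of at least 5, a value that moves with depth, there were 16400 blastema, 16140 intact and 13185 systemically activated peaks. The all-sample list held 491444 peaks covering 199 Mb. Median peak width was 350 bases in intact limb and 329 bases in both systemically activated limb and blastema. The peaks lay on 28 chromosome arms in all 4 lists, with 2.79% of systemically activated, 2.84% of intact and 2.88% of blastema peaks on unplaced sequences.

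Depth differed between the lists in the same order. The lowest background at a summit, which rises with the number of reads behind a list, was 0.375 fragments per base in systemically activated limb, 0.529 in intact limb, 2.49 in blastema and 4.22 in the all-sample list. The blastema background was 6.65 times and the intact background 1.41 times that of systemically activated limb. With the 5th percentile of the background in place of the lowest value, these ratios were 4.80 and 1.08. By that measure the limb lists were close in depth. The median pileup at a summit was 14 fragments in systemically activated limb, 16 in intact limb and 21 in blastema.

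**Figure D1:**
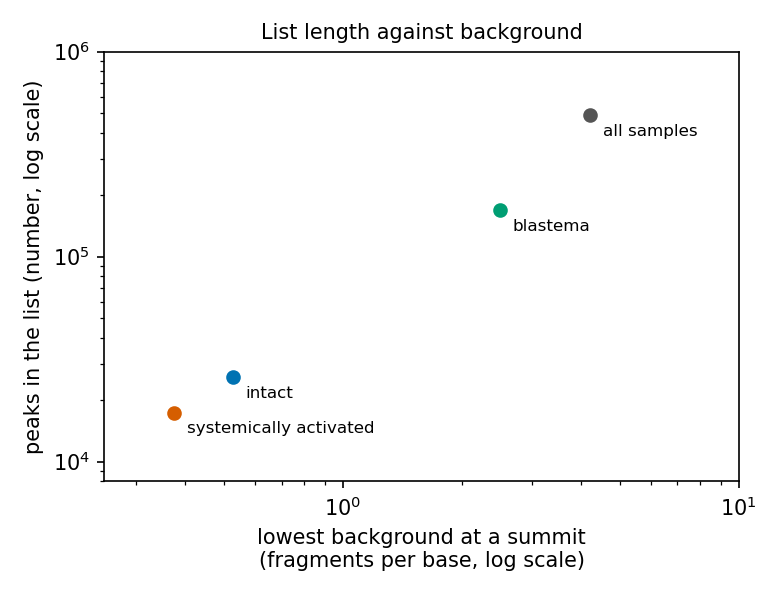
Number of peaks in each list (vertical axis, log scale) against the lowest background at a summit in fragments per base (horizontal axis, log scale), with 1 point per list. The order of the lists is the same on both axes, from systemically activated limb at 0.375 and 17326 peaks to all samples at 4.22 and 491444 peaks.

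The first comparison asked how far the accessible regions of dividing cells in systemically activated limbs were those of homeostatic limbs. Most systemically activated peaks were also intact peaks: 13158 of 17326, or 75.9% (95% interval 75.3 to 76.6), were overlapped by an intact peak by at least 1 base. In the other direction 12965 of 25843 intact peaks, or 50.2% (49.6 to 50.8), were overlapped by a systemically activated peak. That left 4168 peaks in the systemically activated list and 12878 in the intact list without a counterpart in the other limb list. The lists differ in length and depth, so these numbers are not directly comparable. With each list at the length of the shortest, the shares were 66.4% and 64.7%. Sharing was near complete among the strongest peaks and low among the weakest. Of the systemically activated peaks in the highest decile of −log10 q, 99.0% were overlapped by an intact peak, against 45.0% of the lowest decile. The same shares of intact peaks were 95.7% and 13.1%. When 50% of each interval had to be shared, the shares of the lowest deciles were 21.5% and 7.74%, and those of the highest were 91.3% and 85.5%. With each list at the length of the shortest, the lowest deciles had 31.4% and 31.0%, and the highest 98.0% and 97.8%.

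Peaks without a counterpart were weaker and narrower within their own list. Systemically activated peaks that an intact peak overlapped had a median −log10 q of 6.09 and a median width of 376 bases, against 3.74 and 229 bases for those without an overlap. For intact peaks the medians were 7.52 and 487 bases with an overlap, and 4.04 and 260 bases without.

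Named peaks were ranked by fold here and below. A low background raises a fold, so a high rank need not mean a high pileup. Among systemically activated peaks with no intact overlap, the 5 with the highest fold enrichment over background lay on arms 5q, 1p and 7q. The first was on 5q segment 1 from 65137847 to 65138105 with a fold of 10.8 and a −log10 q of 23.4, and the nearest intact peak was 3914 bases away. The second was on 5q segment 2 from 379423809 to 379424025 (fold 9.45). The next were on 1p segment 0 from 94554153 to 94554421 (fold 9.22) and on 1p segment 2 from 24343911 to 24344128 (fold 9.01). The last was on 7q segment 2 from 302100942 to 302101150 (fold 8.91), 920 bases from an intact peak. All 5 were overlapped by a blastema peak. Among intact peaks with no systemically activated overlap, the highest folds were on 10p segment 0 from 26586865 to 26587202 (fold 11.8) and on 13q from 478338969 to 478339361 (fold 11.7). Peaks on 12p from 260209001 to 260209232, on 2q segment 0 from 59058788 to 59059009 and on 9q segment 0 from 143789340 to 143789586 followed, each with a fold of 11.1. These 5 were also overlapped by a blastema peak.

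Both limb lists overlapped the same all-sample peaks more often than draws matched on strength did, by a margin that shrank with finer matching. Of the all-sample peaks, 12873 were overlapped by both limb lists, against a mean of 6561 (95% of draws 6459 to 6661) in 1000 random draws matched on deciles of the all-sample −log10 q, a ratio of 1.96. The highest ratio that the lists allowed in these draws was 2.49. With draws matched on percentiles, a setting chosen after seeing the data, the ratio was 1.17. Strength was thus not held fully constant by deciles. Among peaks with a fold of at least 5 the ratio was 1.08, drawn from only 13089 all-sample peaks. The highest possible ratio changes with the setting, so ratios of different settings are not directly comparable. The ratio was 1.25 at a −log10 q of at least 5 and 2.09 with the all-sample summit inside the limb interval. It was 2.26 with each group list at the length of the shortest, and 4.51 when 50% of each interval had to be shared. The 50% rule keeps only all-sample peaks close in width to a limb peak, and the draws were not matched on width. That could push the ratio upward, which was not tested, so the 4.51 cannot be read as more sharing. Over the settings tried, the share of systemically activated peaks with an intact overlap ran from 54.4%, when 50% of each interval had to be shared, to 78.5% at a −log10 q of at least 5.

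**Figure D2:**
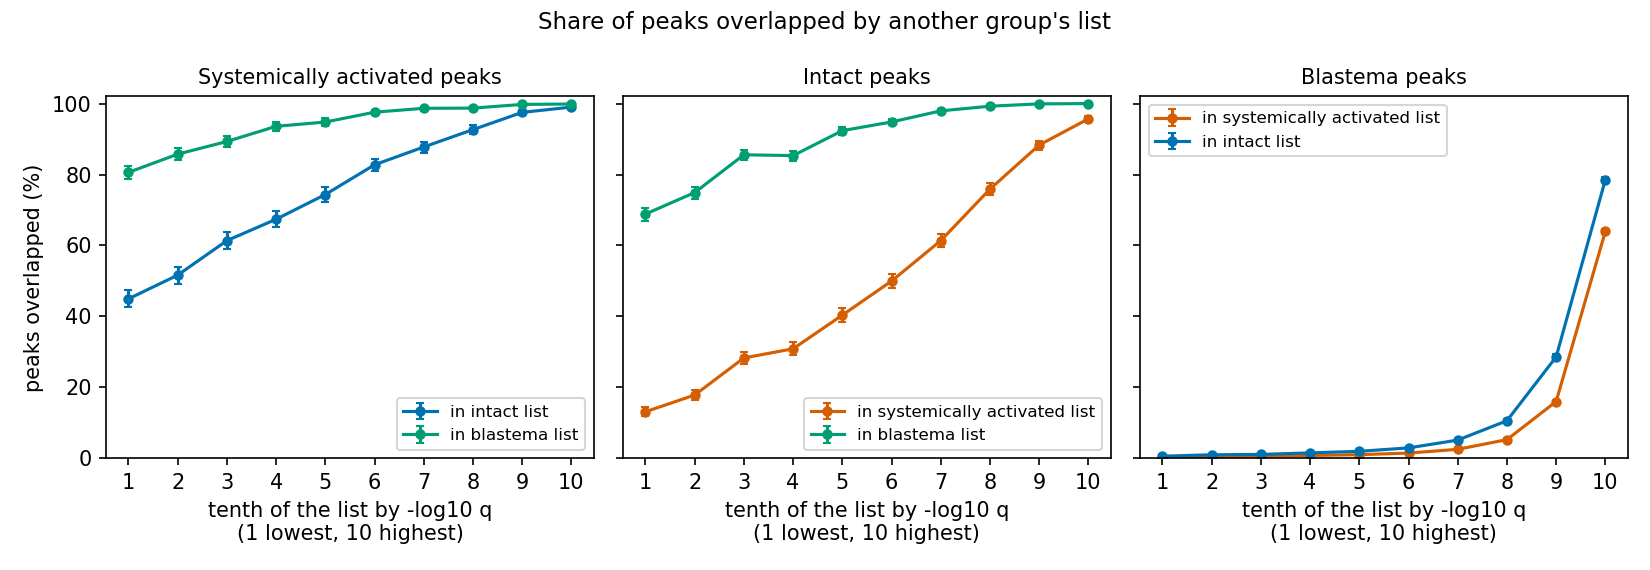
Share of peaks overlapped by at least 1 base by the list of another group (vertical axis, %), by decile of −log10 q within the list (horizontal axis, 1 lowest and 10 highest), for systemically activated, intact and blastema peaks. Points are shares and bars exact 95% intervals, and the shares run from 45.0% to 99.0% for systemically activated peaks in the intact list and from 0.261% to 64.0% for blastema peaks in the systemically activated list.

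The second comparison set systemically activated limb against regenerating tissue. Nearly all systemically activated peaks were overlapped by the whole blastema list, which was 9.72 times as long. A blastema peak overlapped 16264 of 17326, or 93.9% (93.5 to 94.2), and 1062 had no overlap. With each list at the length of the shortest the share was 66.9%, near the 66.4% overlapped by intact peaks in that setting. With the whole lists the share was 99.9% in the highest decile and 80.6% in the lowest. These were 57.6% and 15.2% when 50% of each interval had to be shared, and 72.1% and 35.3% at a fold of at least 5. In the other direction 15533 of 168368 blastema peaks, or 9.23% (9.09 to 9.36), were overlapped by a systemically activated peak, with 64.0% of the highest decile and 0.261% of the lowest. With 50% of each interval shared these were 22.3% and 0.166%, and at a fold of at least 5 they were 92.1% and 2.13%. With each list at the length of the shortest they were 93.1% and 30.6%. Blastema peaks with a systemically activated overlap had a median width of 894 bases and a median −log10 q of 16.6, against 309 bases and 3.97 for the others.

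The blastema peak of highest fold with no systemically activated overlap was on 1p segment 1 from 308812255 to 308812636. It had a fold of 19.5 and a −log10 q of 64.6, and no intact peak overlapped it either. The nearest peak of either limb list was 74941 bases away. The next 4 were on 10p segment 0 from 26586937 to 26587656 and on 13q from 478338971 to 478339452 (fold 15.2 each), on 5q segment 0 from 58612597 to 58612905 (fold 14.9) and on 12p from 260208969 to 260209252 (fold 14.3). An intact peak overlapped each of these 4. Of systemically activated peaks with no blastema overlap, the one of highest fold was on 8p segment 0 from 182526682 to 182527168 (fold 8.78), and an intact peak overlapped it. The other 4 were in no other group list: 10p segment 1 from 136314842 to 136315078 (fold 8.45), 5p segment 1 from 308575115 to 308575391 and 6q segment 1 from 169780380 to 169780740 (fold 8.33 each), and 5q segment 2 from 239348998 to 239349258 (fold 8.11).

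Matched draws could say little about this overlap, since the highest ratio of observed to chance overlap that the lists allowed was 1.07. Both lists overlapped 15545 all-sample peaks against a mean of 15308 (95% of draws 15260 to 15353), a ratio of 1.02, and the ratio turned to 0.989 with draws matched on percentiles. The 93.9% share was 92.3% when the summit had to lie inside a blastema peak and 96.8% at a −log10 q of at least 5. It was 30.7% when 50% of each interval had to be shared and 43.5% among peaks with a fold of at least 5. Median width was 341 bases for systemically activated peaks with a blastema overlap and 894 for blastema peaks with a systemically activated overlap. The 50% rule thus also turned on width. The fold filter kept 13185 of 17326 systemically activated but 16400 of 168368 blastema peaks. The 9.23% share depended on list length as well: it was 63.1% with each list at the length of the shortest. It was 34.2% among peaks with a fold of at least 5 and 3.16% when 50% of each interval had to be shared.

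The third comparison set intact limb against regenerating tissue. Here too most limb peaks were in the blastema list: 23233 of 25843 intact peaks, or 89.9% (89.5 to 90.3), were overlapped by a blastema peak, and 2610 were not. All 2584 peaks of the highest decile were overlapped, against 68.9% of the lowest. When 50% of each interval had to be shared these shares were 76.7% and 19.6%, and at a fold of at least 5 they were 75.3% and 29.6%. Of blastema peaks, 22215, or 13.2% (13.0 to 13.4), were overlapped by an intact peak, with 78.6% of the highest decile and 0.594% of the lowest. With 50% of each interval shared these were 43.4% and 0.279%, and at a fold of at least 5 they were 97.7% and 4.94%. With each list at the length of the shortest they were 97.3% and 34.4%.

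After the 1p peak named above, the blastema peaks of highest fold with no intact overlap were on 6p segment 2 from 396494308 to 396494662 (fold 14.3) and on 3p segment 0 from 6736404 to 6736691 (fold 14.0). Peaks on 4p segment 2 from 188223364 to 188223873 (fold 13.4) and on 10p segment 0 from 205909946 to 205910268 (fold 13.2) followed. None of these was in the systemically activated list. Intact peaks with no blastema overlap were led by peaks on 7q segment 0 from 210689785 to 210690092 (fold 8.50), 7q segment 2 from 14954764 to 14955062 (fold 8.33) and 13p from 134693145 to 134693636 (fold 8.15). The next were on 12q segment 1 from 421977114 to 421977471 (fold 7.85) and on 13q from 374148133 to 374148364 (fold 7.83). No systemically activated peak overlapped these 5. The number of all-sample peaks overlapped by both lists, 22225, was 1.01 times the mean of the matched draws, 22029 (95% of draws 21967 to 22089), where the highest ratio possible was 1.10. With draws matched on percentiles it was 0.986 times. The 89.9% share was 87.6% when the summit had to lie inside a blastema peak and 95.9% at a −log10 q of at least 5. It was 70.7% with each list at the length of the shortest, 42.6% when 50% of each interval had to be shared and 45.0% among peaks with a fold of at least 5. Here too widths differed, with medians of 376 bases for overlapped intact peaks and 827 for overlapped blastema peaks. The 13.2% share was 68.0% with each list at the length of the shortest, 43.4% among peaks with a fold of at least 5 and 6.54% when 50% of each interval had to be shared.

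The fourth comparison asked whether peaks held by 1 limb list were found in blastema. By overlap of at least 1 base most were, from either limb list. Of the 4168 systemically activated peaks with no intact overlap, 3225, or 77.4% (76.1 to 78.6), were overlapped by a blastema peak. Of the 12878 intact peaks with no systemically activated overlap, 10390, or 80.7% (80.0 to 81.4), were. The odds ratio was 0.819 (Fisher's exact test, two-sided p = 4.66e-06, over peaks of these lists, which are not independent along a chromosome). Peaks shared by both limb lists were in the blastema list in 99.1% of cases, counted from either side. These values depended on the settings. The shares were 77.4% and 79.2% with the summit inside the other interval, and 87.5% and 91.9% at a −log10 q of at least 5. They were 16.3% and 33.6% when 50% of each interval had to be shared, and 19.0% and 31.8% among peaks with a fold of at least 5. With each list at the length of the shortest they were 30.3% and 44.0%. The direction turned when intact peaks were dropped at random to bring the limb lists to equal length: the median odds ratio was 1.82 over 100 draws (range 1.74 to 1.91), with shares of 88.4% and 80.7%. It was 0.529 when the weakest intact peaks were dropped in their place. The odds ratio of the whole lists was 0.902 (0.827 to 0.985) within deciles of each peak's own −log10 q. Within deciles of the all-sample −log10 q the odds ratio was 0.977 (0.852 to 1.12), where the difference could not be told from none. That value covers only 16475 of the 17046 peaks, those overlapped by an all-sample peak, so it mixes stratification with removal of peaks. Both stratifications and both equal-length settings of the limb lists alone were chosen after seeing the data.

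The fifth comparison placed the group lists on the common set of all-sample peaks. All 3 group lists overlapped 12756 all-sample peaks, with a median −log10 q of 24.6. These peaks made up 2.60% of the long all-sample list, and at a fold of at least 5 the number was 3974 of 13089. Their high −log10 q was built in: it is computed with the reads of the same groups, and the shallow limb lists call mainly strong sites. Of the 16368 all-sample peaks overlapped by the systemically activated list, the 12756 were the larger part. A further 9469 were overlapped by the intact and blastema lists, 2789 by the systemically activated and blastema lists, and 117 by both limb lists and not by blastema. The blastema list alone overlapped 130434 (26.5%, median −log10 q 5.18), the intact list alone 1841 and the systemically activated list alone 706. In all, 2664 all-sample peaks, or 0.542%, were overlapped by a limb list and not by the blastema list. The remaining 333332 (67.8%) were in no group list and had the lowest median −log10 q, 2.97, which the shared reads build in as well. At a fold of at least 5 the all-sample list held 13089 peaks. Of these, 700 were in a limb list and not in the blastema list, and 1383 were in no group list.

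The 5 blastema peaks with the highest fold among those that both limb lists overlapped were spread over 4 chromosome arms. They lay on 3p segment 1 from 237846463 to 237846864 (fold 25.8 in blastema), on 3p segment 1 from 367593423 to 367593818 (fold 23.4) and on 3q segment 0 from 130527972 to 130528498 (fold 22.9). The others lay on 9q segment 0 from 329360509 to 329360990 (fold 22.2) and on 5q segment 0 from 20446186 to 20446768 (fold 22.2). At the first of these the overlapping peaks had a fold of 25.8 in the intact list and 23.0 in the systemically activated list, and at the second 25.2 and 24.7. At the 3q peak the folds were 27.6 and 24.6, at the 9q peak 19.7 and 15.5, and at the 5q peak 17.7 and 12.2. Folds move with depth, so these values do not measure a change in accessibility between groups.

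**Figure D3:**
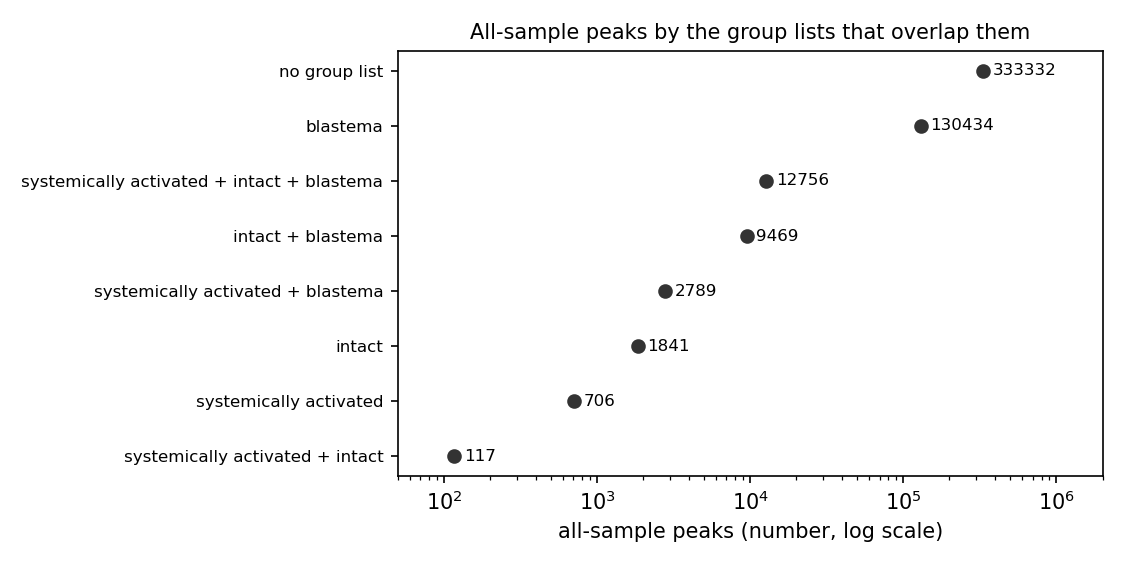
Number of all-sample peaks (horizontal axis, log scale) by the group lists that overlap them (vertical axis), with 1 point and its count per class. Peaks in no group list (333332) and in the blastema list alone (130434) are the most frequent, and 117 are shared by the limb lists without blastema.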

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

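The odds ratio of 0.819 and the backgrounds of the lists were planned; the pileup scaling, the site ratios, the equal-length lists and the stratified odds ratios were chosen after the result they bear on was seen, and the bounds that decide them were set or changed after first values were known.

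The background of the all-sample list was higher than the group lists account for, and the all-sample −log10 q used for matching and stratifying rests on it: its lowest background was 4.22 fragments per base against 3.40 for the sum of the 3 group lists, an excess of 0.824 and a ratio of 1.24. Another genome size setting would leave local backgrounds equal to their sum, yet over 2584 sites with summits within 50 bases and a background above the lowest in all 4 lists they were 1.08 times the sum, and 1.112 times in the quartile of lowest background, which argues against that setting as the whole source. Duplicates kept in the all-sample call alone would raise summit pileups above the sum, and their median ratio was 0.858 (0.847 at the 107 sites with summits within 5 bases). Reads in the all-sample call beyond those of the group lists may be a source and stay open, because 92.6% of the lowest quartile (598 of 646 sites, 90.3 to 94.5, not independent of each other) lay above the sum in background while 96.4% of all sites lay below it in pileup, which extra reads alone would not give, and no biological explanation was tested. A first criterion, that the 5th percentile of the site ratios exceed 1, left the genome size and the extra reads undecided (0.987) and was replaced after that was seen.

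The blastema list was much longer than the limb lists. Scaled to the systemically activated depth, blastema pileups gave an expected 21315 calls, 1.23 times that list, where the lists as given differ 9.72-fold. Scaled to the intact depth they gave 36842 calls, 1.426 times the intact list in place of 6.52-fold, and with the 5th percentile of the background as depth the ratios were 1.89 and 1.52. A difference in depth could therefore account for most of the difference in length, by a bound of 2 set after the first ratios were known, and the size of the upward bias of this scaling was not measured. Whether dividing blastema and wound epidermis cells have more accessible regions stays open and was not tested apart from depth.

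Systemically activated peaks with no intact overlap were in the blastema list less often than the reverse set, with an odds ratio of 0.819. Unequal lengths of the limb lists may be a source: at equal length the odds ratio was 0.529 when the weakest intact peaks were dropped and 1.82 when intact peaks were dropped at random. Each way of dropping pushes the ratio in its own direction, the first by removing intact peaks with low blastema overlap and the second by leaving systemically activated peaks without their counterpart, so length cannot be told apart from a difference in biology. Weaker peaks in the systemically activated set may also be a source, with an odds ratio of 0.902 (0.827 to 0.985) stratified by each peak's own −log10 q and 0.977 (0.852 to 1.12) by the all-sample −log10 q. The first measure is on a different depth scale in each list. The second contains the blastema reads and covers only peaks with an all-sample overlap, so neither decides. First readings of 0.529 and 0.902 as evidence against these sources were withdrawn.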

How the results depend on the processing

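Limb lists at equal length (by strength or at random), draws matched on percentiles, the pileup scaling with either background and both stratifications were chosen after seeing the data, and all other settings before. No paired analysis was possible because each group has 1 list and no values per sample, and for the same reason no replicate was left out. Alternatives for gene promoters, annotated features and motifs were not run. The limb-list odds ratio stayed under 1 in the planned settings, from 0.385 to 0.901, and at 0.529 at equal length by strength. It turned to 1.82 with intact peaks dropped at random to equal length, where the blastema share of systemically activated peaks without a counterpart was 88.4%, and its interval reached 1 when stratified by all-sample −log10 q (0.977). The ratio of observed to chance overlap of the limb lists stayed above 1, from 1.08 to 4.51. The highest value came with 50% reciprocal overlap, where draws not matched on width could push the ratio upward, which was not tested. All 35 named entries kept their state in the settings run on them. For entries defined by having no overlap only merging could change it. The other settings ask for more overlap or shorten lists, and these strong entries pass the filters. Apart from merging, the outcome was thus fixed for them and is no check. Using named arms alone left every share within its 95% interval and every count within 1.5 times. Only 2.73% to 2.88% of the peaks of a list lay on unplaced sequences, so this setting could hardly change a result and is little check. The 5th percentile of the background moved the relative depths from 6.65 to 4.80 and from 1.41 to 1.08. It moved the scaled blastema calls over the systemically activated list from 1.23 to 1.89. A bound of 1.5 times is too wide to test the ratio of 1.41, and at 1.08 the limb lists hardly differed. In blastema the 5th percentile was the lowest background itself, 2.49, with 8.74% of peaks at it. Only 1.04% of systemically activated and 4.07% of intact peaks stood at theirs, so unlike backgrounds are compared. Each share of a highest decile stayed above that of its lowest decile with 50% reciprocal overlap, at fold of at least 5 and with every list at the length of the shortest. Shallow limb lists limit which weak peaks can be called there. Except where a setting removes peaks or asks for more overlap, the cause of a change was not tested.

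Shares are given in the order systemically activated in intact, intact in systemically activated, systemically activated in blastema, intact in blastema, blastema in systemically activated, blastema in intact, then the blastema shares of systemically activated and intact peaks without a counterpart. With 50% reciprocal overlap they were 54.4%, 36.5%, 30.7%, 42.6%, 3.16%, 6.54%, 16.3% and 33.6%. At −log10 q of at least 5 they were 78.5%, 53.3%, 96.8%, 95.9%, 14.1%, 20.4%, 87.5% and 91.9%. At fold of at least 5 they were 64.4%, 52.1%, 43.5%, 45.0%, 34.2%, 43.4%, 19.0% and 31.8%. With every list at the length of the shortest they were 66.4%, 64.7%, 66.9%, 70.7%, 63.1%, 68.0%, 30.3% and 44.0%. With summits inside the other interval, the shares that moved were the first 6 and the last, at 69.2%, 42.7%, 92.3%, 87.6%, 7.61%, 11.1% and 79.2%. Merging within 500 bases moved intact in systemically activated to 51.0%, intact in blastema to 89.5%, the blastema shares to 9.80% and 13.9%, and the last share to 79.6%. With the limb lists alone at equal length, the limb shares were 66.4% and 64.7%, intact in blastema 96.2%, blastema in intact 9.62%, and the last pair 82.7% and 90.0%.

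The observed over chance overlap with blastema fell below 1 for systemically activated and intact peaks at −log10 q of at least 5 (0.988 and 0.988), at fold of at least 5 (0.966 and 0.972) and with draws matched on percentiles (0.989 and 0.986). At −log10 q of at least 5 the lists held 13913 intact (7.02 Mb), 9492 systemically activated (4.19 Mb), 63771 blastema (40.6 Mb) and 121403 all-sample peaks (79.6 Mb). At fold of at least 5 they held 16140 intact, 13185 systemically activated, 16400 blastema (11.2 Mb) and 13089 all-sample peaks (10.8 Mb). All-sample peaks in no group list, in blastema alone, in all 3 lists and in a limb list without blastema then numbered 60538, 45492, 7320 and 703 at −log10 q of at least 5, and 1383, 4613, 3974 and 700 at fold of at least 5.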

Other observations

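All tests in this part were chosen after seeing the data, and the regional count of 0 was first read as evidence against a difference and then left open.

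Regions accessible in all 3 groups were unevenly spread along the chromosomes, but somewhat less so than blastema peaks of like strength. Over 1374 windows of 20 Mb the median number of blastema peaks overlapped by both limb lists was 7, and the densest decile, 137 windows, held 29.6% of the 12379 such peaks. As many blastema peaks drawn at random gave 24.4% (95% of 1000 draws 23.7 to 25.0), and draws matched on deciles of the blastema −log10 q gave 30.5% (30.0 to 31.0). Draws matched on its percentiles gave 32.0% (31.5 to 32.5). The window with the most was 1q segment 2 from 420000001 to 440000000 with 78, followed by 9q segment 2 from 300000001 to 320000000 with 68. The windows 9q segment 2 from 280000001 to 300000000 and 12q segment 0 from 200000001 to 220000000 held 61 each. Of the 100 peaks with the highest fold, 6 lay on 1p segment 0 from 200000001 to 210000000 in each of the 3 group lists. That window held 0.151% of intact, 0.137% of systemically activated and 0.118% of blastema peaks. Its median background was also lower than that of the list, which raises a fold: 1.54 against 2.10 in intact limb, 1.22 against 1.62 in systemically activated limb and 3.54 against 5.08 in blastema.

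No region differed between the limb lists past the adjusted threshold. Of 210 windows with at least 20 peaks held by 1 limb list, 0 passed an exact binomial test against the genome-wide share after Benjamini-Hochberg adjustment (smallest adjusted p = 0.173), and 16 had an unadjusted p under 0.05. Of 28 chromosome arms 0 passed the same exact test (smallest adjusted p = 0.235), with 4 under 0.05 unadjusted. The window with the smallest p was at the start of 12p, from 1 to 20000000, with 16 systemically activated and 15 intact peaks without a counterpart, a ratio of 3.29 relative to the genome-wide numbers. The next were on 6q segment 3, where the window from 380000001 to 400000000 held 2 and 39 and the window from 360000001 to 380000000 held 2 and 35. The lowest ratio, 0.124, was at the start of 11p, from 1 to 20000000, with 1 and 25. A regional difference between the limb lists was the explanation tested, and the count of 0 leaves it open, because window ratios from 0.124 to 3.29 show how little such small counts can exclude.

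Arm 13q differed from the genome-wide share in opposite directions depending on the blastema peaks it was compared with. Against the strongest 17326 blastema peaks it was the 1 arm of 28 that passed, with a ratio of 0.835 for intact (adjusted p = 0.0155, exact binomial test) and 0.828 for systemically activated (adjusted p = 0.0308), and 0 windows passed in either comparison (13 and 12 unadjusted). By the same exact test, against the whole blastema list, its ratios were 1.21 (adjusted p = 3.32e-05) and 1.20 (adjusted p = 0.00149). There it was 1 of 10 arms that passed for intact peaks and 1 of 7 for systemically activated peaks, and 14p had higher ratios, 1.25 and 1.33. With the whole list, 25 of 1308 and 18 of 1304 windows passed. All of these belong to the 10 sets of regional tests that were run. The exact test treats peaks as independent, although they are unevenly spread. Stronger blastema peaks were also more concentrated: matched draws gave 30.5% in the densest decile, against 24.4% for any blastema peaks. The whole blastema list holds many weaker peaks, so its counts mix strength with region. The tests of the limb lists share the same blastema peaks and are not separate results.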
